A study of Mus musculus with 24 samples.

How the data were processed

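Liver non-parenchymal cells of male BALB/c mice were enriched for CD11b and Ly6G with magnetic beads after 70% hepatectomy or a sham laparotomy, and poly-A RNA was sequenced in 24 libraries, 3 for each of 2 operations on each of postoperative days 1, 2, 3 and 4. The authors trimmed adapters with cutadapt, aligned reads with STAR 2.4.2a to GRCm38 and counted them with HTSeq, and the deposited table holds raw counts per gene symbol for each library. The annotation release, the strand setting and any filter applied by the authors are not stated. The values were checked to be whole numbers whose totals differ between libraries, from 10390216 to 16949088. The table lists 46477 symbols, of which 27740 have at least 1 count, and replicates of a group correlated across genes at Pearson's r from 0.766 to 0.990 on the log scale. Genes are not independent replicates, and the depth limits counting error only, which is small beside the spread between libraries of a group for genes above a few CPM.

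Differential expression was tested with edgeR 4.0.16 in R 4.3.3 as a quasi-likelihood F test in 1 fit of all 24 libraries over 8 groups with 16 residual degrees of freedom. Libraries were scaled with TMM, low genes were removed with filterByExpr, which left 14325 genes, and p values were adjusted by the Benjamini-Hochberg method at 0.05. The comparisons were these: hepatectomy against sham on each of the 4 days, their mean with equal weights, the interaction of operation and day, the effect at POD4 minus that at POD1, and the differences between days in sham and after hepatectomy. All tests were two-sided. The SE printed beside a fold change is its size divided by the square root of F and is approximate. The groups, comparisons, gene lists, naming rule and alternatives were fixed before the data were examined.

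The 18 gene lists covered primary granules, secondary and tertiary granules, neutrophil receptors, suppressive effectors, angiogenic factors, hepatocyte mitogens, inflammatory cytokines, interferon-stimulated genes, S phase, G2 and M phase, glycolysis and hypoxia, oxidative phosphorylation, the unfolded protein response, immediate-early genes, NADPH oxidase and antioxidants, lipid metabolism, apoptosis, and complement and acute-phase receptors. The 16 marker lists covered neutrophils, hepatocytes, Kupffer cells and macrophages, monocytes, sinusoidal endothelium, stellate cells and fibroblasts, T cells, NK cells, B cells, plasma cells, MHC class II and dendritic cells, erythroid cells, eosinophils, basophils and mast cells, platelets, and cholangiocytes. Some genes are on more than 1 list, such as Sod2, Icam1, Cybb and Marco. Each list was tested with camera in limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 136 tests of 34 lists and 4 days, and separately over the 34 lists for the mean over days. Camera with an estimated correlation and fry were run beside it, and members were counted past 0.05 both over all genes and adjusted over the list alone.

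The naming rule took, on each day, genes past 0.05 whose 3 hepatectomy libraries all lay above or all below the 3 sham libraries, with a mean of at least 5 CPM over the 6 and no predicted, clone, immunoglobulin or T cell receptor symbol, and of these the 8 with the highest and the 8 with the lowest fold change. Chance alone gives such a separation for 10% of genes. Where none passed, the 3 with the lowest p were given as values. For the mean over days the rule required the same sign on all 4 days in place of separation, and for the tests between days it took the 8 genes with the lowest p. Up to 4 members of each list with the lowest p were eligible, and 19 genes of suppressive or angiogenic myeloid cells were tabulated on every day. Coordinates were looked up in GENCODE M21, where 13662 of the tested symbols (95.4%) were found. A fold against a group at 0 counts was bounded with a floor of 3 counts in each library of that group.

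The alternatives chosen at that stage were DESeq2 1.42.0, limma voom with quality weights, DESeq2 size factors within edgeR, library size alone, no low-count filter, a filter of at least 5 CPM in at least 3 libraries, fits of a day or operation by itself, a block of replicate numbers, and leaving out each library in turn. Alternatives for normalized values were not run, since the table holds counts. Chosen after seeing the data were an endothelial score, the mean log2(CPM + 1) of the 19 sinusoidal markers, as a covariate, and a fit without the 4 libraries of POD3 and POD4 at or below the widest gap of that score. The score is circular for endothelial genes, and at POD1 it extrapolates, since the hepatectomy libraries lie below every sham library. At POD2 they do so too, at 10.12 to 10.35 against 10.62 to 10.83. The scores of the operations therefore overlap on neither day.

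The model was tested on simulated counts with 200 changed genes, drawn at the depths of these libraries from a gene mean shared by all of them. These counts held no endothelial difference between libraries and no correlation between genes, so their false calls do not carry over to the real libraries. The model recovered between 3% and 11% of genes changed 2-fold and between 73% and 80% of those changed 8-fold on a day, with 3 to 6 false calls. With the endothelial score it recovered 42% to 74% of the former and 99% to 100% of the latter. Those runs were simulated with the spread estimated in the fit with the score and without an endothelial effect. The higher recovery is therefore not a measure for libraries that differ in endothelial content.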

Results

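RNA was measured in cells carrying CD11b and Ly6G, the surface pair used to define granulocytic myeloid-derived suppressor cells (G-MDSCs), which were taken from mouse liver with magnetic beads. The mice had either 70% of the liver removed (hepatectomy) or a laparotomy without resection (sham). Livers were sampled on postoperative day (POD) 1, 2, 3 or 4, which gave 8 groups of 3 libraries and 24 libraries in all. Each library held between 10390216 and 16949088 counted reads, and between 16231 and 19581 genes had at least 1 count. Levels are given in CPM, the counts of a gene relative to the scaled library total, as mean ± SD of 3 libraries, and fold changes as log2 of hepatectomy over sham ± an approximate standard error (SE) from the edgeR fit.

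The sorted fractions differed in the transcripts of other liver cells, shown here for Stab2 and S100a8 in CPM of the unscaled library total. Stab2, a scavenger receptor of liver sinusoidal endothelium, stood at 10.5, 10.2 and 29.8 CPM in the hepatectomy libraries of POD1 and at 73.4, 386 and 3871 CPM in sham POD1. It stood between 1663 and 4062 CPM in all libraries of POD2 and in sham POD3. S100a8, a calcium-binding protein abundant in neutrophils, ran the other way. It stood at 18550 to 20230 CPM in hepatectomy POD1 and at 20280 CPM in replicate 3 of sham POD4, down to 748 CPM in replicate 3 of sham POD2. An endothelial score, the mean log2 level of 19 sinusoidal markers, split the libraries into 9 at or below 8.36 and 15 at or above 9.97. The 9 were all 3 hepatectomy libraries of POD1, replicate 1 of hepatectomy POD3 and POD4, replicates 1 and 2 of sham POD1, and replicates 2 and 3 of sham POD4. The first principal component held 68.0% of the variance and parted the same 9 libraries from the other 15.

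**Figure D1:**
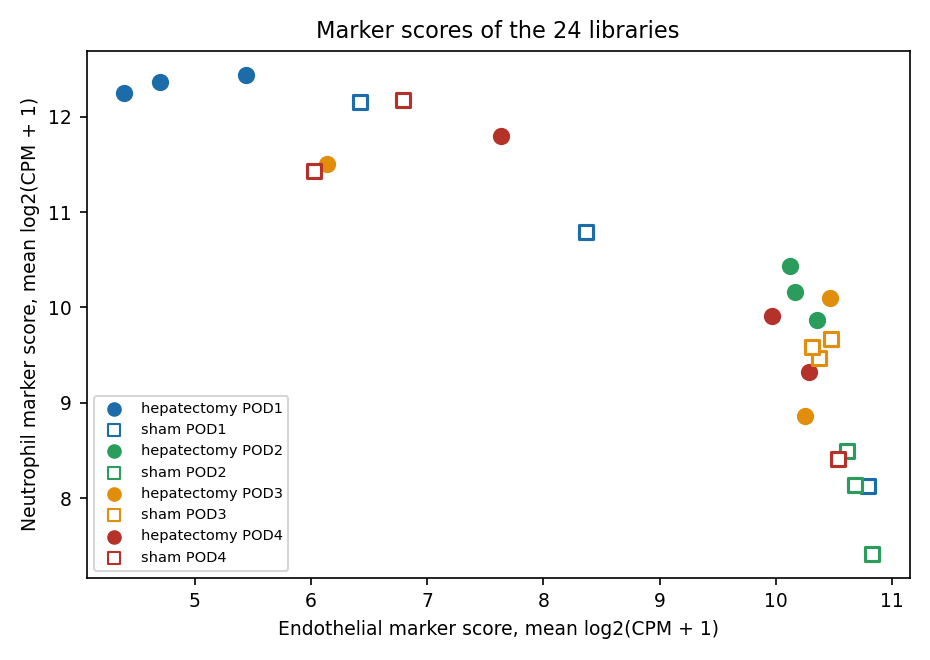
Neutrophil marker score against endothelial marker score, both as mean log2(CPM + 1) over a fixed marker list, with a point for each of the 24 libraries (filled circles hepatectomy, open squares sham, colour by day). The hepatectomy libraries of POD1 lie at the low end of the endothelial score, from 4.39 to 5.45, while sham POD1 spreads over 6.42, 8.36 and 10.79.

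The first comparison asked what differed in liver G-MDSCs a day after hepatectomy against a sham operation. More inflammatory genes rose than fell at POD1, and more endothelial, B cell and S phase genes fell than rose. Csf3, which encodes the granulocyte growth factor G-CSF, rose from 0.899 ± 1.09 to 1068 ± 259 CPM (log2 10.32 ± 1.52, adjusted p = 0.000114). Il10, an anti-inflammatory cytokine made by suppressive myeloid cells, rose from 3.49 to 180 CPM (log2 5.73 ± 0.89, adjusted p = 0.000172). Cd274, which encodes the checkpoint ligand PD-L1, rose from 72.8 to 854 CPM (log2 3.55 ± 0.72, adjusted p = 0.00147). Kdr, the VEGF receptor of endothelium, fell from 1390 ± 1851 to 12.5 ± 3.66 CPM (log2 -6.80 ± 1.46, adjusted p = 0.0022). Arg1, the arginase used as a marker of suppressive myeloid cells, fell from 89.1 to 13.1 CPM (log2 -2.77 ± 0.78, adjusted p = 0.00995).

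Of 14325 genes tested, 5866 passed an adjusted p of 0.05 at POD1, 1857 of them higher and 4009 lower after hepatectomy, or 610 higher and 8066 lower with library size alone. The 3 hepatectomy libraries of POD1 also stood apart from sham POD1 in mitochondrial counts (0.708% to 0.778% against 1.67% to 2.07%), in the share of the top 10 genes (17.9% to 19.01% against 6.63% to 12.8%) and in genes detected (16231 to 16704 against 17636 to 18928). These differences follow the operation on that day and were not separated from it. Among the genes highest by the naming rule, Il1f6, an interleukin 1 family cytokine, stood at 15.6 ± 3.89 CPM and at 0 counts in every sham POD1 library. That is at least 61.02-fold higher, against a floor of 3 counts per library. Muc20, a membrane mucin, rose by log2 10.13 ± 1.24, Mfsd7a, a member of a transporter family, by 7.31 ± 0.67, and Slc28a3, a nucleoside transporter, by 7.07 ± 1.29. Cst7, a cysteine protease inhibitor of leukocytes, rose by 7.01 ± 1.04, Orm1, an acute-phase glycoprotein also stored in neutrophil granules, by 6.65 ± 1.34, and Ereg, a ligand of the epidermal growth factor receptor, by 6.56 ± 1.10. The genes with the lowest fold changes were Tbxa2r, the thromboxane receptor (-7.97 ± 1.77), Il13ra2, a decoy receptor of interleukin 13 (-7.71 ± 1.83) and Gpr155 (-7.49 ± 1.63). They were followed by Rgs7bp (-7.09 ± 1.63), Ralgps2, an exchange factor for Ral (-6.87 ± 1.41), Kdr, Reep1 (-6.77 ± 1.76) and Bahcc1 (-6.61 ± 1.35). Replicate 3 of sham POD1 held most of the sham level of these 8, as with Tbxa2r at 88.5 CPM there against 4.83 and 17.2 CPM in replicates 1 and 2. Csf3 lies on chromosome 11 from 98701263 to 98703629 of GRCm38, and Kdr on chromosome 5 from 75932827 to 75978458.

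The median log2 change of all genes at POD1 was -0.42 with TMM scaling, -0.32 with median-of-ratios size factors and -1.44 with library size alone, so list medians at POD1 are given relative to it unless stated otherwise. Relative to all genes, each list median named in the following POD1 paragraphs kept its sign under all 3 scalings. The subtraction removes most of what a scaling adds to all genes, so this kept sign does not test the normalization. The unfolded protein list, for instance, stood at 1.15, 1.13 and 1.04 after subtraction in the order given. Before subtraction it stood at 0.72, 0.81 and -0.40. The inflammatory cytokine, chemokine and NF-kB list stood 2.63 above the median of all genes, and 24 of its 44 measured members rose and 1 fell (25 and 1 adjusted over the list alone). Sod2, a mitochondrial superoxide dismutase, rose by 5.54 ± 0.65, Traf1, a signalling adaptor of TNF receptors, by 5.26 ± 0.81, Icam1, an adhesion molecule, by 3.15 ± 0.45, and Nfkb1, a subunit of NF-kB, by 2.38 ± 0.28. The list was higher by camera (adjusted p = 4.19e-14), with adjusted p = 0.326 with an estimated correlation. The secondary and tertiary granule list stood 2.74 above all genes, with 9 of 27 members higher and 0 lower (9 and 0 adjusted over the list alone). Its lowest p values were those of Orm1, Cybb, the catalytic subunit of the phagocyte NADPH oxidase (3.33 ± 0.88), Chil3, a chitinase-like protein (5.40 ± 1.60), and Olfm4, a granule glycoprotein (3.99 ± 1.25). Camera gave adjusted p = 2.59e-07 for this list, and adjusted p = 0.499 with an estimated correlation. The fraction of endothelial transcripts differed between the same groups, with a sinusoidal marker median 4.54 below all genes.

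The list of suppressive effectors had 9 members higher and 2 lower of 32, the same adjusted over the list alone, and stood 1.61 above all genes at POD1 (camera adjusted p = 3.73e-05, adjusted p = 0.499 with an estimated correlation). Besides Il10, Cd274 and Cybb it held Ptges, a prostaglandin E synthase, at log2 4.24 ± 0.94. Among genes fixed for every day, Il6, a cytokine that primes hepatocytes for division, rose by 2.85 ± 0.92 (adjusted p = 0.0201). Nos2, the inducible nitric oxide synthase, was at 4.56 ± 1.88 (adjusted p = 0.0586) and Itgam, which encodes CD11b, at 2.15 ± 0.88 (adjusted p = 0.0564), and neither passed. S100a8 (1.93 ± 1.06) and S100a9 (1.64 ± 1.03), the subunits of calprotectin, Tnf (1.95 ± 0.90) and Cxcl2 (2.04 ± 1.01) did not pass either. The same held for Osm (1.59 ± 0.79), Prok2 (2.68 ± 1.70), Il1b (1.12 ± 0.84), Mmp9 (1.08 ± 0.88) and Arg2 (0.91 ± 0.75). Ly6g (0.37 ± 1.13), Vegfa (0.12 ± 0.51), Tgfb1 (0.04 ± 0.29) and Hgf (-0.78 ± 0.43) did not pass. Of 28 neutrophil receptors 4 rose and 3 fell (2 and 3 adjusted over the list alone), with the list 1.69 above all genes (camera adjusted p = 0.00029, adjusted p = 0.616 with an estimated correlation). Fpr1, the receptor of formylated bacterial peptides, rose by 3.39 ± 1.05, while C5ar2, a second receptor of complement C5a, fell by 1.34 on the log2 scale and Itga4, an integrin chain, by 2.48. The primary granule list had 0 higher and 1 lower of 12 (Igfbp4, a binder of insulin-like growth factors, -5.46 ± 1.24) and was not called (camera adjusted p = 0.351). Before subtraction its median was positive and its mean negative.

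Secreted growth factors moved both ways at POD1. Of 25 angiogenic factors 5 rose and 5 fell, the same adjusted over the list alone. Among them were Edn1, the vasoconstrictor endothelin 1 (5.46 ± 0.71), Anxa3, an annexin of neutrophil granules (3.64 ± 0.52), Itgb3, an integrin chain (2.19 ± 0.35), and Nrp1, a VEGF co-receptor (-6.24 ± 1.29). The angiogenic list was 1.21 above all genes (camera adjusted p = 0.0301, adjusted p = 0.251 with an estimated correlation). Of 25 hepatocyte mitogens and regeneration cytokines 6 rose and 7 fell (8 and 7 adjusted over the list alone), and the list was not called (camera adjusted p = 0.413). Ereg and Inhba, a subunit of activins (4.07 ± 0.90), rose, while Pdgfb, a platelet-derived growth factor chain, fell by 2.14 on the log2 scale and Wnt9b, a Wnt ligand of liver endothelium, by 2.65. In the interferon-stimulated list 17 of 66 rose and 5 fell, the same adjusted over the list alone, at 1.03 above all genes (camera adjusted p = 0.00119, adjusted p = 0.601 with an estimated correlation). Helz2, a nuclear co-activator, rose by 2.13 ± 0.53 and Eif2ak2, the kinase PKR, by 1.23 ± 0.25, while Ly6e, a surface protein, fell by 2.22 on the log2 scale.

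Stress and metabolic lists stood above the median of all genes at POD1. Of 29 genes of the unfolded protein and integrated stress response 11 rose and 2 fell (12 and 2 adjusted over the list alone), at 1.15 above all genes. Xbp1, Atf4 and Atf6, transcription factors of this response, rose from 231 to 1305, from 228 to 647 and from 65.3 to 182 CPM. Herpud1, a factor of protein degradation at the endoplasmic reticulum, rose by 1.60 ± 0.30. Of 40 glycolysis and hypoxia genes 11 rose and 3 fell, the same adjusted over the list alone. Among them were Pfkfb3, which makes an activator of phosphofructokinase (3.40 ± 0.75), Ero1l, an oxidase of the endoplasmic reticulum (2.56 ± 0.55), Pfkp, a phosphofructokinase (2.20 ± 0.57), and Hk1, a hexokinase (1.49 ± 0.27). Of 32 apoptosis and survival genes 10 rose and 3 fell, the same adjusted over the list alone. Fas, a death receptor, was at 2.35 ± 0.45, Cflar, an inhibitor of caspase 8, at 2.29 ± 0.26 and Ripk3, a kinase of necroptosis, at 2.15 ± 0.28. Of 31 NADPH oxidase and antioxidant genes 13 rose and 5 fell (14 and 6 adjusted over the list alone). Nqo1, a quinone reductase, was at 2.13 ± 0.44, Txnrd1, a thioredoxin reductase, at 2.14 ± 0.47 and Cat, catalase, at -2.27 ± 0.30. Camera called these 4 lists higher (adjusted p = 0.000628, 0.000389, 0.000143 and 0.000178 in that order), with adjusted p = 0.251, 0.57, 0.299 and 0.424 with an estimated correlation.

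Of 41 lipid genes 12 rose and 9 fell (14 and 11 adjusted over the list alone). The 4 with the lowest p were Acsl5 (2.31 ± 0.22) and Acsl4 (2.07 ± 0.22), which activate fatty acids, Hmgcs1, an enzyme of sterol synthesis (2.61 ± 0.28), and Insig1, a sterol sensor (2.23 ± 0.28). Of 28 complement and acute-phase genes 5 rose and 4 fell, the same adjusted over the list alone. Saa3, an acute-phase apolipoprotein, rose to 3890 ± 371 CPM, Marco, a scavenger receptor of phagocytes, was at 4.97 ± 0.93 and Cd59a, an inhibitor of the membrane attack complex, was at -5.31 ± 1.30. Of 39 immediate-early and dissociation genes 5 rose and 5 fell, the same adjusted over the list alone. They included Socs3, a feedback inhibitor of cytokine signalling (1.17 ± 0.38), and Hsph1, a heat shock protein (-3.47 ± 0.72). Camera called these 3 lists higher (adjusted p = 0.00434, 0.00661 and 0.0154), with adjusted p = 0.251, 0.361 and 0.631 with an estimated correlation. The oxidative phosphorylation list was not called (9 of 73 higher and 5 lower, 8 and 3 adjusted over the list alone, camera adjusted p = 0.132), and its median and mean before subtraction differed in sign. Before subtraction, the medians of 10 lists lay above 0 at POD1 with TMM and below 0 with library size alone: primary granule, angiogenic, mitogen, interferon, glycolysis, oxidative phosphorylation, unfolded protein, immediate-early, lipid, and apoptosis.

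Of 40 S phase genes 2 rose and 18 fell at POD1, the same adjusted over the list alone. E2f1, a transcription factor of S phase entry, was at -4.56 ± 0.77 and Mcm2, a subunit of the replicative helicase, at -3.48 ± 0.81. The list was lower by camera (adjusted p = 0.0137, adjusted p = 0.708 with an estimated correlation). Of 44 G2 and M phase genes 1 rose and 11 fell (0 and 8 adjusted over the list alone), with Cenpa, the centromeric histone, at -1.83 ± 0.28. Mki67, on the same list, went the other way, at 20.1 to 28.3 CPM of the unscaled total in the hepatectomy libraries against 5.16 to 14.3 CPM in sham. This list was not called (camera adjusted p = 0.0606). Before subtraction the medians were -1.48 and -1.62, or -1.43 and -1.25 with the genes at 0 in all hepatectomy POD1 libraries set to their bound.

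Markers of several other cell types were lower at POD1. Of 19 sinusoidal endothelial markers 18 fell and 0 rose, the same adjusted over the list alone, including Ehd3, a membrane-trafficking protein (-5.95 ± 1.31), Bmp2, a regulator of iron metabolism (-5.62 ± 1.31), and Tek, the angiopoietin receptor (-5.43 ± 1.28). Of 14 B cell markers 13 fell and 0 rose (14 and 0 adjusted over the list alone). Cd79b and Cd79a, the signalling chains of the B cell receptor, were at -5.10 ± 0.65 and -4.10 ± 0.63. The B cell median before subtraction was -4.26, or -4.16 with Ms4a1, which was at 0 counts in the hepatectomy libraries, set to its bound. Of 20 stellate cell and fibroblast markers 13 fell and 0 rose, the same adjusted over the list alone, with Colec11, a collectin (-4.84 ± 0.54), and the collagens Col1a2 (-2.36 ± 0.38) and Col3a1 (-1.92 ± 0.36). Of 16 MHC class II and dendritic cell genes 10 fell and 0 rose, the same adjusted over the list alone, with Clec9a, a receptor of dendritic cells, at -5.12 ± 1.03. Of 11 plasma cell markers 7 fell and 1 rose, the same adjusted over the list alone, with Igha, the heavy chain of immunoglobulin A, at -3.51 ± 0.92. Camera called these 5 lists lower (adjusted p = 0.000278, 2.28e-08, 0.00026, 0.00218 and 0.0335), with adjusted p = 0.601, 0.275, 0.354, 0.424 and 0.499 with an estimated correlation. Of 19 Kupffer cell and macrophage markers 13 fell and 2 rose (14 and 2 adjusted over the list alone), with the phagocytic receptor Mertk at -3.79 ± 0.80 and the mannose receptor Mrc1 at -4.97 ± 1.14. This list too was called lower (camera adjusted p = 0.0447, adjusted p = 0.683 with an estimated correlation).

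Of 17 monocyte markers 5 fell and 3 rose (6 and 3 adjusted over the list alone), and the camera direction was opposite to the median before subtraction. The chemokine receptors Cx3cr1 and Ccr2 were at -3.69 ± 0.79 and -2.76 ± 0.65, and fibronectin, Fn1, at -3.71 ± 0.79. Of 5 eosinophil markers 3 fell (Siglecf, an inhibitory lectin, -3.52 ± 0.97), and of 3 basophil and mast cell markers 2 fell (Gata2, a transcription factor, -3.85 ± 1.10). Of 11 platelet markers 3 fell (Gp1ba, a receptor of von Willebrand factor, -2.06 ± 0.44), and of 8 erythroid markers 1 fell (Fech, the last enzyme of haem synthesis, -2.44 ± 0.32). In each of these lists 0 members rose, and the counts adjusted over the list alone were the same. Of 9 T cell markers 1 rose and 2 fell, the same adjusted over the list alone. Of 3 NK cell markers 1 rose (Ccl5, a chemokine, 3.77 ± 0.77) and 1 fell (1 and 2 adjusted over the list alone). Of 29 hepatocyte markers 3 fell and 0 rose (1 and 0 adjusted over the list alone). Of 7 cholangiocyte markers 1 rose and 0 fell (0 and 0 adjusted over the list alone). None of these 9 marker lists was called by camera, whose adjusted p ran from 0.126 for eosinophils to 0.916 for monocytes and T cells. The 14 neutrophil markers had 0 members past the test by edgeR, also adjusted over the list alone, with a median 1.57 above all genes (camera adjusted p = 0.00426, adjusted p = 0.616 with an estimated correlation).

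Without replicate 3 of sham POD1, the library richest in endothelial transcripts there, 3324 genes passed at POD1, and without replicate 1 of hepatectomy POD1 3795. Without that sham library the camera calls of neutrophil receptors, angiogenic factors, immediate-early genes and neutrophil markers ended. Before subtraction their medians were 0.76, 0.56, 0.39 and 0.63, against 1.27, 0.79, 0.645 and 1.15 with all libraries. Suppressive effectors went from 1.19 to 0.70, interferon-stimulated genes from 0.61 to 0.35 and apoptosis genes from 0.785 to 0.46, also before subtraction. Lipid genes went from 0.27 to 0.01, endothelial markers from -4.965 to -2.99 and all genes from -0.42 to -0.29. The angiogenic call also ended without replicate 1 of sham. The Kupffer cell call ended without replicate 1 or 3 of hepatectomy or replicate 1 or 2 of sham, and the plasma cell call without replicate 1 of hepatectomy or replicate 1 or 2 of sham. Before subtraction the Kupffer cell median then lay between -1.90 and -1.78, against -2.05 with all libraries. The plasma cell median then lay between -2.65 and -2.29, against -2.65. With the endothelial score in the model, an alternative chosen after seeing the data, 17 inflammatory genes rose and 3 fell, while of the suppressive effectors 4 rose and 7 fell and of the neutrophil receptors 1 rose and 9 fell. In the same fit 2 secondary and tertiary granule genes rose and 2 fell (camera adjusted p = 0.687, adjusted p = 0.991 with an estimated correlation). Before subtraction the median of this list was 0.06, against 2.32 without the score. All genes had a median of -0.16 in that fit. Of the interferon-stimulated genes 10 rose and 18 fell, and of the glycolysis genes 5 rose and 9 fell. Before subtraction the neutrophil marker median turned from 1.15 to -0.65, with 0 members higher and 2 lower (camera adjusted p = 0.281). S phase was no longer called, with 2 higher and 5 lower at a median of -0.65 before subtraction (camera adjusted p = 0.594). The G2 and M phase list was called lower (camera adjusted p = 0.0402, adjusted p = 0.9 with an estimated correlation).

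**Figure D2:**
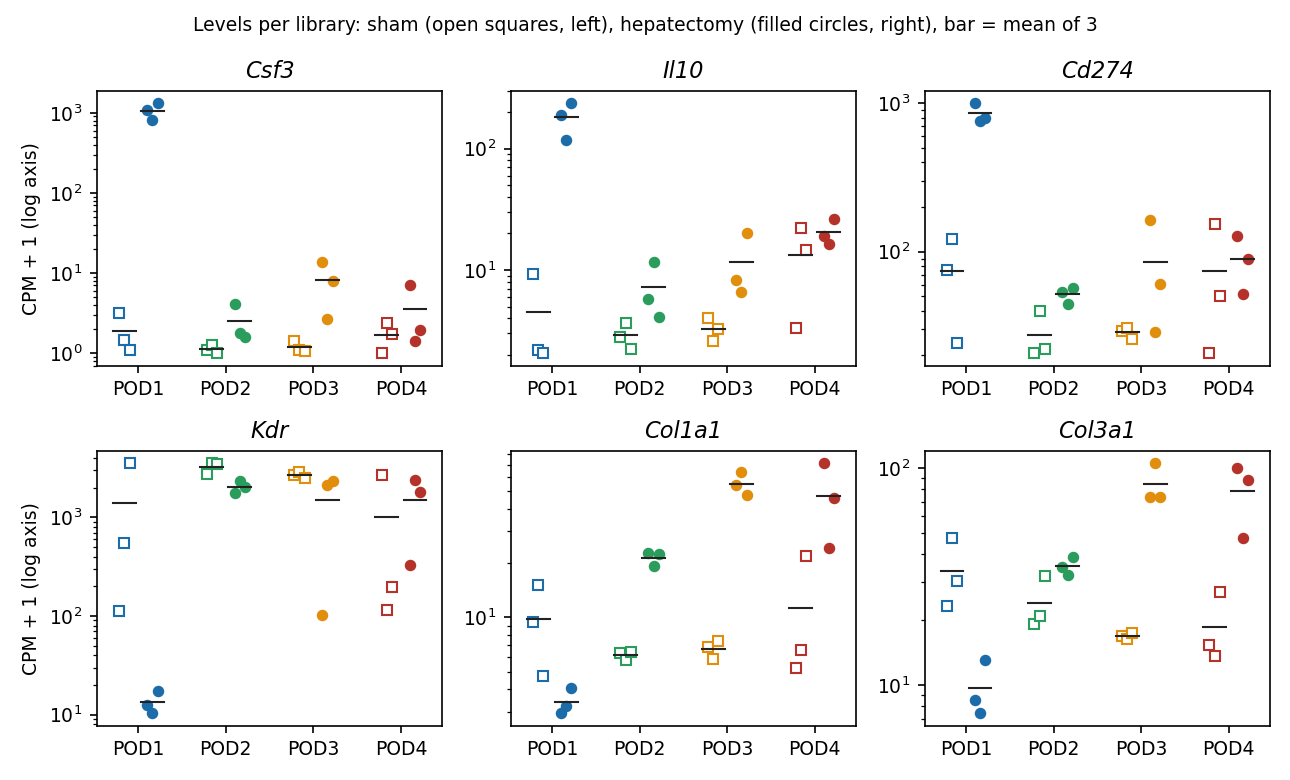
Levels of 6 genes per library as CPM + 1 on a log axis, by postoperative day, with sham as open squares, hepatectomy as filled circles and a bar at the mean of 3. Csf3 reaches a mean of 1068 CPM and Il10 of 180 CPM at POD1 after hepatectomy, and Col1a1 and Col3a1 lie above sham in every hepatectomy library of POD3.

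The second comparison put hepatectomy against sham at POD2. Srxn1, which encodes the antioxidant enzyme sulfiredoxin, rose from 20.6 ± 4.17 to 75.9 ± 24.03 CPM (log2 1.88 ± 0.35, adjusted p = 0.0416). Dcn, decorin, a proteoglycan of stellate cells and fibroblasts, fell from 186 ± 41.2 to 57.4 ± 15.8 CPM (log2 -1.70 ± 0.32, adjusted p = 0.0471), and Col14a1, a fibril-associated collagen, from 32.9 to 10.9 CPM (log2 -1.60 ± 0.30). Tmem56 fell by 2.55 on the log2 scale and Khk, the kinase that starts fructose breakdown, by 1.60. In all 14 genes passed by edgeR over the 24 libraries, 5 higher and 9 lower, or 3 higher and 1 lower with library size alone. DESeq2 called 195 genes (106 higher), limma voom with quality weights 4686 (2727 higher) and edgeR on the libraries of POD2 alone 3816 (2113 higher). The count was 2, 1 and 1 without replicate 1, 2 or 3 of hepatectomy, 0 without replicate 2 of sham and 1 without replicate 3 of sham. The other 4 higher ones, named after their values were seen, were Thy1, a surface protein of T cells and fibroblasts (3.16 ± 0.42), and Il21r, the receptor of interleukin 21 (2.81 ± 0.51), with Tubb3, a tubulin (6.41 ± 1.12), and Fam71f2 (5.95 ± 1.11).

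No member of the S phase list passed over all genes at POD2 by edgeR, but 21 of 40 were higher adjusted over the list alone. The list median was 1.44 (camera adjusted p = 2.44e-20, adjusted p = 0.251 with an estimated correlation). The G2 and M phase list had a median of 1.56 with 0 of 44 members past the test in either way (camera adjusted p = 4.82e-15, adjusted p = 0.334 with an estimated correlation). Of the inflammatory list 12 of 44 were higher adjusted over the list alone and 0 over all genes, at a median of 1.79 (camera adjusted p = 2.65e-20, adjusted p = 0.251 with an estimated correlation). Adjusted over the list alone, 10 of 40 glycolysis genes, 7 of 25 mitogens, 3 of 32 suppressive effectors and 3 of 25 angiogenic factors were higher, against 0 in each over all genes. Arg1, at 213 against 15.3 CPM, had a log2 of 3.80 ± 0.81 (adjusted p = 0.0669) and did not pass. Ccl2, a monocyte chemokine, was at 2.60 ± 0.52 (adjusted p = 0.0542) and Cxcl3, a neutrophil chemokine, at 6.48 ± 1.48 (adjusted p = 0.102). Vegfa was at 1.90 ± 0.52 (adjusted p = 0.211) and Il6 at 3.24 ± 0.92 (adjusted p = 0.222). The neutrophil marker median was 2.12 with 0 of 14 members past the test (camera adjusted p = 4.36e-09, adjusted p = 0.334 with an estimated correlation). The endothelial median was -0.49. Of the stellate and fibroblast markers Dcn fell and 0 rose over all genes, and 7 were lower and 2 higher adjusted over the list alone (camera adjusted p = 9.31e-05, adjusted p = 0.334 with an estimated correlation).

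With the endothelial score in the model, 1149 genes passed at POD2, where the scores of the operations do not overlap. The naming rule on that fit gave Cxcl3 (5.97 ± 1.11), Thbs1, the matrix protein thrombospondin 1 (4.22 ± 1.06), Vcan, the proteoglycan versican (4.13 ± 1.01), Spp1, osteopontin (3.92 ± 0.85), and Arg1 (3.73 ± 0.77, adjusted p = 0.00874) among the highest. Among the lowest were Angpt2, a ligand of the angiopoietin receptor, at -2.35 and Twist1, a mesenchymal transcription factor, at -2.16.

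**Figure D3:**
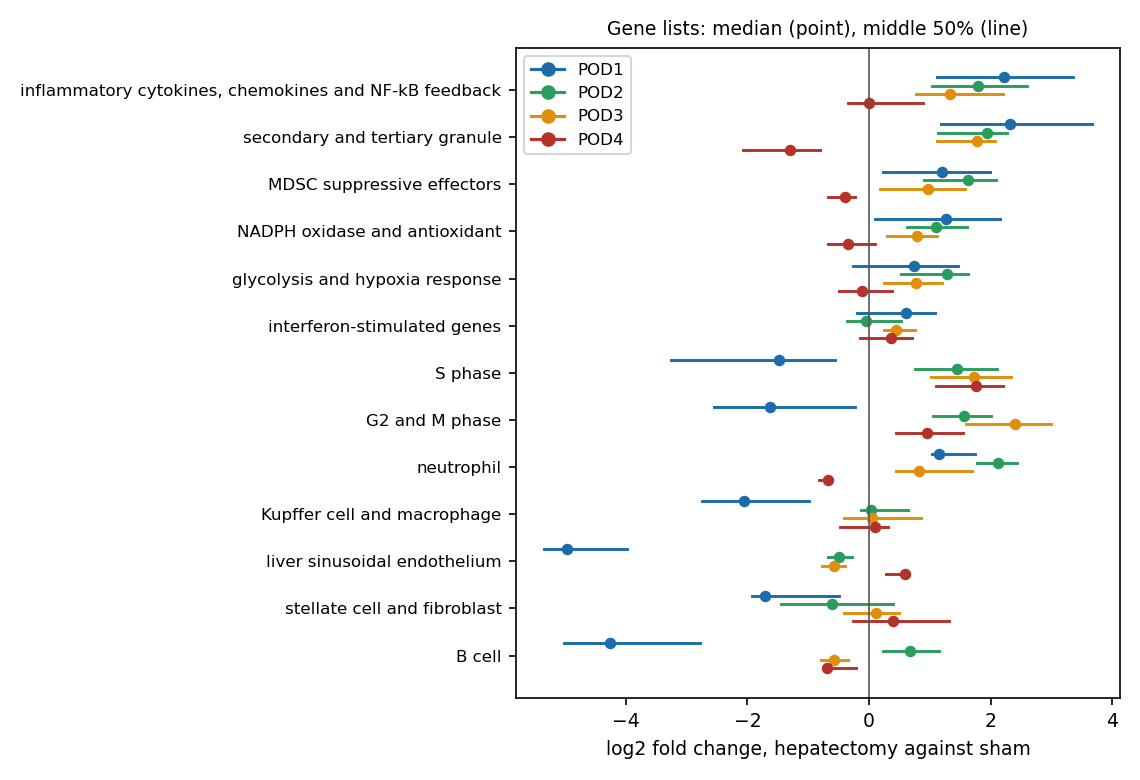
Median log2 fold change of hepatectomy against sham for 13 gene and marker lists at each postoperative day, with a line over the middle 50% of members. The inflammatory list lies at 2.21, 1.79, 1.33 and 0.00 on POD1 to POD4 and the S phase list at -1.48, 1.44, 1.72 and 1.76, while all genes lie at -0.42 on POD1.

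The third comparison put hepatectomy against sham at POD3. Col1a1, a chain of type I collagen, rose from 5.71 ± 0.80 to 54.1 ± 8.34 CPM (log2 3.24 ± 0.54, adjusted p = 0.0404). Col3a1, type III collagen, rose from 15.8 ± 0.53 to 83.1 ± 18.5 CPM (log2 2.39 ± 0.36, adjusted p = 0.0298). Col1a1 lies on chromosome 11 from 94936224 to 94953042 and Col3a1 on chromosome 1 from 45311538 to 45349706. Thy1, named after its values were seen, was the only other gene past the test, at 2.69 ± 0.80 against 0.437 ± 0.085 CPM (log2 2.60 ± 0.42, adjusted p = 0.0404). The related chain Col1a2 was at 1.93 ± 0.36 (adjusted p = 0.0754). Col1a1, Col3a1 and Col1a2 are all on the stellate cell and fibroblast marker list. Whether they came from such cells in the sorted fraction or from the sorted cells was not tested. The median of that list was 0.12 at POD3. Its camera call ended without replicate 3 of hepatectomy, at a median of -0.04, or without replicate 1 of sham, at 0.03.

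Both cell cycle lists were called higher at POD3 by camera at the preset correlation, but not with an estimated correlation. Of 44 G2 and M phase genes 32 were higher adjusted over the list alone and 0 over all genes by edgeR, at a median of 2.4 (camera adjusted p = 2.67e-37, adjusted p = 0.149 with an estimated correlation). Of 40 S phase genes 25 were higher adjusted over the list alone and 0 over all genes, at a median of 1.72, or 0.82 without replicate 2 of hepatectomy (camera adjusted p = 9.59e-31, adjusted p = 0.189 with an estimated correlation). Top2a, a topoisomerase of dividing cells, was at 3.40 ± 0.86 (adjusted p = 0.146) and Uhrf1, a factor that maintains DNA methylation in S phase, at 3.38 ± 0.76 (adjusted p = 0.122), and neither passed over all genes. Of the inflammatory list 12 of 44 were higher adjusted over the list alone and 0 over all genes, at a median of 1.33 (camera adjusted p = 1.74e-17, adjusted p = 0.275 with an estimated correlation). Il6 was at 3.94 ± 0.95 (adjusted p = 0.122), Arg1 at 3.37 ± 0.79 (adjusted p = 0.122) and Il10 at 2.23 ± 0.77 (adjusted p = 0.315). The hepatocyte markers had 22 of 29 members higher adjusted over the list alone and 0 over all genes, at a median of 2.10 (camera adjusted p = 2.28e-12, adjusted p = 0.358 with an estimated correlation). This rested on replicate 1 of hepatectomy POD3, without which the median was 0.00 with 0 members past the list test by edgeR. Without any single sham library of that day 0 members passed either, at medians of 2.05 to 2.17. Albumin, Alb, stood at 646 CPM of the unscaled total in that replicate, 111 and 50.6 CPM in the other 2 and 39.1 to 74.6 CPM in sham. MHC class II and dendritic cell genes had a median of -0.94, or -1.74 without replicate 2 of hepatectomy, with 0 members past the test (camera adjusted p = 6.95e-07, adjusted p = 0.251 with an estimated correlation).

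With the endothelial score in the model 1255 genes passed at POD3. Among the highest by the naming rule were Uhrf1 (3.55 ± 0.69), Lif, a cytokine of the interleukin 6 family (3.85 ± 0.80), and Saa3 (3.73 ± 0.68). Hlf, a circadian transcription factor, at -2.21 and Fgl2, a prothrombinase, at -1.92 were among the lowest. Without replicate 1 of hepatectomy POD3, which had a low endothelial score, 18 genes passed. When the 4 libraries of POD3 and POD4 with a low score were left out, also an alternative chosen after seeing the data, 166 passed. Without replicate 3 of hepatectomy POD3, or without any single sham library of that day, 0 passed. DESeq2 called 277 genes at POD3 and limma voom with quality weights 3776.

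**Figure D4:**
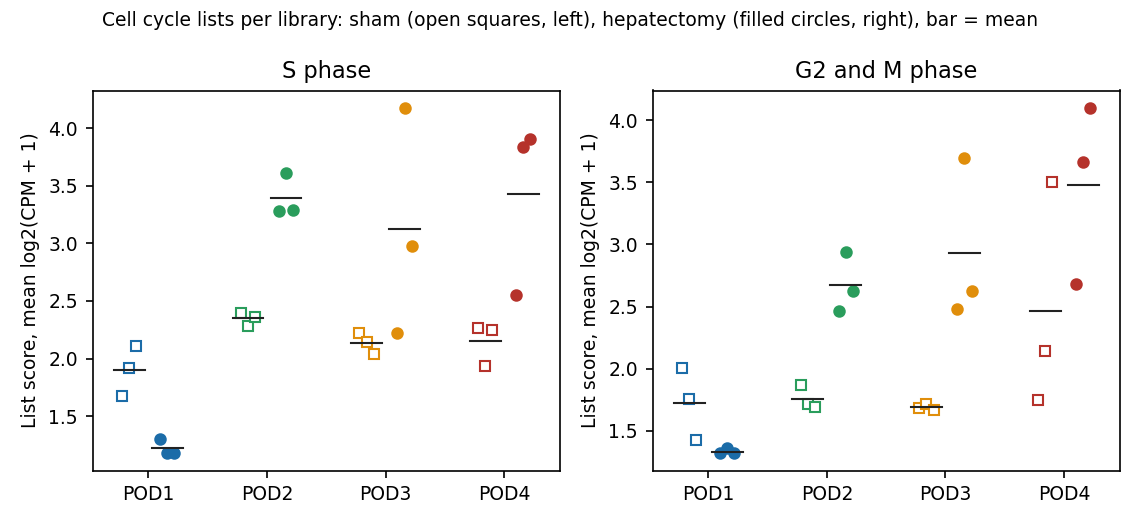
Mean log2(CPM + 1) of the S phase list (left panel) and of the G2 and M phase list (right panel) per library by postoperative day. Sham libraries are open squares, hepatectomy filled circles and bars the mean of 3, and the hepatectomy libraries of POD1 lie below all sham libraries of that day in the S phase panel, and those of POD2 above.

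The fourth comparison put hepatectomy against sham at POD4. None of the 3 genes with the lowest p by the naming rule passed. Col3a1 stood at 77.6 ± 27.4 against 17.6 ± 7.26 CPM (log2 2.14 ± 0.35, adjusted p = 0.0592). Il21r stood at 10.3 ± 2.87 against 1.504 ± 0.786 CPM (log2 2.78 ± 0.51, adjusted p = 0.133), and Tubb6, a tubulin, at 50.4 ± 9.63 against 13.2 ± 1.61 CPM (log2 1.94 ± 0.38, adjusted p = 0.264). Of 40 S phase genes 28 were higher adjusted over the list alone and 0 over all genes, at a median of 1.76 (camera adjusted p = 2.84e-34, adjusted p = 0.149 with an estimated correlation). Plasma cell markers had 8 of 11 members lower adjusted over the list alone and 0 over all genes, at a median of -2.11, or -1.26 without replicate 2 of sham (camera adjusted p = 7.39e-10, adjusted p = 0.149 with an estimated correlation). Igha stood at 129 ± 152 against 799 ± 846 CPM, Jchain, the joining chain of immunoglobulins, at 24.6 ± 24.8 against 147 ± 154 CPM, and Iglc1, a light chain, at 2.13 ± 1.52 against 21.8 ± 12.1 CPM.

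The G2 and M phase median at POD4 was 0.96 with 0 of 44 members past the test (camera adjusted p = 4.38e-14, adjusted p = 0.334 with an estimated correlation). Replicate 3 of sham POD4 stood apart, with a mean of 3.5 over this list against 1.74 and 2.14 in the other sham libraries and 2.69 to 4.10 after hepatectomy. Without it the median was 2.27, while it was 0.55 without replicate 3 of hepatectomy and 0.58, with no call, without replicate 1 of sham. The secondary and tertiary granule median was -1.30 with 0 of 27 members past the test (camera adjusted p = 6.48e-06, adjusted p = 0.57 with an estimated correlation). Its members Ltf, lactoferrin, and Ngp, a granule protein, stood at 449 ± 447 against 3231 ± 4670 CPM and at 1025 ± 1079 against 7478 ± 10950 CPM. This call rested on replicate 3 of sham, without which the median was 0.37 and not called, and the median was -2.59 without replicate 1 of hepatectomy. The list median was 0.08 with the endothelial score in the model, and the list was not called (camera adjusted p = 0.359). The endothelial median was 0.59, with 2 of 3 sham libraries and 1 of 3 hepatectomy libraries of that day at a low endothelial score. It was 3.14 without replicate 1 of sham, and 1.04 and 0.10 without replicate 1 or 2 of hepatectomy. Without replicate 2 or 3 of sham it was 0.06 and 0.11, and the camera call of this list ended. Of the stellate and fibroblast list 3 members were higher adjusted over the list alone and 0 over all genes (camera adjusted p = 0.000415, adjusted p = 0.361 with an estimated correlation), a call that ended without replicate 1 of hepatectomy or replicate 2 of sham. The inflammatory list had a median of 0.00 below and a mean of 0.34 above 0, with camera higher (adjusted p = 0.0055, adjusted p = 0.683 with an estimated correlation) except without replicate 1 of hepatectomy or of sham. Its median was -0.32 and -0.35 without these, 0.98 without replicate 2 of sham, and 1.10 with the endothelial score in the model. No gene passed at POD4 by edgeR, which gave 689 at an unadjusted p under 0.05, while DESeq2 called 31 genes and limma voom with quality weights 7250. With the endothelial score in the model 26 passed, with Col1a1 (2.52 ± 0.45, adjusted p = 0.0186), Col3a1 (2.15 ± 0.34), Col1a2 (1.69 ± 0.34) and Il21r (2.55 ± 0.45) among the named.

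The mean over the 4 days weighted the difference of each day equally, so a gene can pass through POD1 alone. Csf3 (5.25 ± 0.66), Ereg (4.61 ± 0.56), Cxcl3 (4.12 ± 0.66), Saa3 (4.01 ± 0.57) and Ikbke, a kinase of NF-kB and interferon signalling (3.77 ± 0.56), rose, as did Thbs1 (3.71 ± 0.60) and Adora2b, an adenosine receptor (3.53 ± 0.40). The lowest were Twist1 (-2.87 ± 0.63), Plxdc1, a receptor of tumour endothelium (-2.82 ± 0.58), and Nr1d1, a circadian repressor (-2.47 ± 0.52). Then came Tle2, a co-repressor (-2.37 ± 0.54), Thrsp, a factor of lipid synthesis (-2.35 ± 0.32), Aass, an enzyme of lysine breakdown (-2.31 ± 0.59), Cntfr, a receptor of ciliary neurotrophic factor (-2.27 ± 0.57), and Galnt15 (-2.25 ± 0.35). By the naming rule each of these genes had the same sign of the difference on all 4 days. In all 2009 genes passed, 865 higher and 1144 lower, or 578 higher and 2472 lower with library size alone. Without replicate 3 of sham POD4 3073 passed.

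Of 44 inflammatory genes 27 rose and 0 fell in the mean over days (34 and 1 adjusted over the list alone), with camera adjusted p = 1.18e-29 and adjusted p = 0.0786 with an estimated correlation. Of 25 angiogenic factors 6 rose and 2 fell (8 and 2 adjusted over the list alone), with camera adjusted p = 0.000204 and adjusted p = 0.0279 with an estimated correlation. It was the only list call, of those on the 4 days and in their mean, that held with an estimated correlation. Of 40 S phase genes 15 rose and 0 fell (22 and 0 adjusted over the list alone). Of 32 suppressive effectors 9 rose and 0 fell (15 and 0 adjusted over the list alone). Camera called both lists higher (adjusted p = 6.06e-09 and 2.8e-09), with adjusted p = 0.345 and 0.332 with an estimated correlation. Of 14 B cell markers 8 fell and 0 rose (13 and 0 adjusted over the list alone, camera adjusted p = 6.16e-08, adjusted p = 0.18 with an estimated correlation). Of 17 monocyte markers 4 rose and 0 fell, the same adjusted over the list alone (camera adjusted p = 0.000225, adjusted p = 0.345 with an estimated correlation).

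The interaction test asked whether the effect of hepatectomy differed between days, and 1244 genes passed it. Tmem45a2, the gene with the lowest p, was at log2 5.63 ± 0.37 on POD1 and at -0.60, 0.27 and -1.19 on POD2, POD3 and POD4 (adjusted p = 8.95e-07). Slc9a8, a sodium and proton exchanger (3.12 ± 0.21 on POD1), Limk2, a kinase of the actin cytoskeleton (3.00 ± 0.23), Pwp1 (3.49 ± 0.25) and Id2, an inhibitor of helix-loop-helix factors (2.87 ± 0.24), stood between -0.46 and 0.70 on the later days. Sec22b, a vesicle fusion protein (1.78 ± 0.16 on POD1), and Tifa, an adaptor of NF-kB signalling (4.47 ± 0.40), stood between -0.40 and 0.74 then. Fam102a was at -2.40 ± 0.20 on POD1 and between -0.19 and 0.04 later. Between POD1 and POD4 alone the effect differed for 4078 genes, with 2785 higher at POD4 than at POD1 and 1293 lower, or 6492 higher and 292 lower with library size alone. Without replicate 1, 2 or 3 of hepatectomy POD1 the interaction held 453, 625 and 500 genes, and without replicate 1 or 2 of sham POD1 1900 and 798. It held 2198 without replicate 1 of hepatectomy POD3, 783 and 789 without replicate 2 or 3 of hepatectomy POD4, and 4744 without replicate 1 of sham POD4. The difference between POD4 and POD1 held 2165 and 2633 genes without replicate 1 or 2 of hepatectomy POD1, and 2078 and 2289 without replicate 2 or 3 of hepatectomy POD4. It held 1836 without replicate 3 of sham POD1, 7100 without replicate 1 of sham POD4 and 2235 without replicate 3 of sham POD4.

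After hepatectomy 6422 genes differed between days, and 3053, 3521 and 3604 without replicate 1, 2 or 3 of POD1. Those with the lowest p stood highest at POD1. Tmem45a2 was at 42.3 ± 3.75 CPM on POD1 and between 0.593 and 1.05 on the other days (adjusted p = 1.75e-10). Slc9a8 was at 175 ± 33.3 against 15.5 to 18.4 CPM, Limk2 at 482 ± 54.8 against 37.5 to 48.9 CPM. Pwp1 was at 99.3 ± 21.8 against 11.3 to 14.2 CPM, and Id2 at 987 ± 40.6 against 128 to 171 CPM. Mfsd7a stood at 245 ± 31.7 against 1.22 to 7.47 CPM, Pim2, a survival kinase, at 104 ± 30.3 against 1.84 to 3.97 CPM and Prkd3, a protein kinase D, at 569 ± 143 against 69.4 to 77.9 CPM.

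In sham, the gene with the lowest p between days was Rab15, a small GTPase of endosomes, at 7.37 ± 7.38 CPM on POD1 and between 0.0677 and 0.320 later (adjusted p = 0.0561). Postn, the matrix protein periostin, stood at 18.1 ± 5.33, 9.46 ± 2.08, 6.07 ± 0.96 and 4.83 ± 1.30 CPM on POD1 to POD4 (adjusted p = 0.0957). Edn1 stood at 5.79 ± 2.77 on POD1 and between 0.378 and 1.75 CPM later (adjusted p = 0.187). Jchain, Vegfa, Serpinb2, an inhibitor of plasminogen activators, Havcr2, the checkpoint receptor TIM-3, and Ccdc117 followed, each at adjusted p = 0.193. By edgeR 0 genes passed between sham days, with 2810 at an unadjusted p under 0.05, while DESeq2 called 1513 and limma voom with quality weights 10039. Without replicate 1 of sham POD4 edgeR called 3449 genes, and without replicate 3 of sham POD1 it called 2597.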

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

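The tests of technical explanations in this part were all chosen after the results were seen, while the interaction tests were planned. The effect of hepatectomy differed between days for 1244 genes by the interaction test and between POD4 and POD1 for 4078 genes, both in edgeR. Relabelling the operation within days gave at least as many genes in 8 of 100 draws for each, with 3810 and 7076 as the highest of the others, so chance is not excluded by this test. The genes with the lowest p of the difference were Tmem45a2 (adjusted p = 8.95e-07), Slc9a8 (adjusted p = 2.11e-06), Limk2 (adjusted p = 1.23e-05), Pwp1 (adjusted p = 1.93e-05), Id2 (adjusted p = 7.59e-05), Sec22b and Fam102a (each adjusted p = 0.000143) and Tifa (adjusted p = 0.000164). Of these, 7 were higher at POD1 than on the later days in their effect and Fam102a was lower. No formal outlier test was run on groups of 3 libraries, but each library was left out in turn. The interaction then held 453 to 4744 genes and the difference between POD4 and POD1 1836 to 7100, so both counts depend on single libraries.

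At POD1, 4009 genes were lower and 1857 higher after hepatectomy. A lower share of endothelial cells in these libraries, which a sort for CD11b and Ly6G would be meant to remove, may account for part of the lower genes, since 69.4% of them rose with the endothelial score within the groups of POD2 to POD4, against 33.3% of genes not called. Of the higher genes 52% fell with the score within those groups and 9.26% rose, against 42.8% and 33.3% of genes not called. These slopes rest largely on the 4 low-score libraries of POD3 and POD4. Within hepatectomy POD2, sham POD2 and sham POD3 the score spanned only 10.12 to 10.35, 10.62 to 10.83 and 10.31 to 10.48. All 14 neutrophil markers fell with the score, so these shares cannot tell endothelial content from neutrophil content. With the score in the model the median of the lower genes moved from -2.59 to -0.82, with 1593 called lower and 105 higher, and that of the higher genes from 1.32 to 0.88, with 1087 called higher. The fit with the score does not decide on the higher genes, since the hepatectomy libraries of POD1 lie below every sham library in the score. In addition, 15 of 100 draws, the real score included, called as many genes or more at POD1. With library size alone the higher genes had a median of 0.37 (middle 50% from -0.09 to 1.20) and 607 were called higher, so the composition factors of the normalization stay open too, as does an effect of hepatectomy on the sorted cells.

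At POD2 to POD4 the cell cycle lists were called higher after hepatectomy by camera at the preset correlation, but not with an estimated correlation. The tables argue against the difference in endothelial content as the whole cause, under a slope of the score shared by both operations. With the score in the model all 6 list medians lay between 0.97 and 2.48 with their lower quartile above 0. No camera call held there with an estimated correlation (adjusted p = 0.622 to 0.653), and at POD2 the operations do not overlap in the score. At POD4 the S phase mean was 2.55 in the low-score hepatectomy library against 3.84 and 3.91 in the others. In sham POD4 the low-score libraries stood at 1.93 and 2.25 against 2.26. A shared slope cannot remove transcripts of other cells that cycle only after hepatectomy, so the fit does not decide on these. The values also argue against progenitors that express Mpo and Elane. Mpo reached at most 0.668 CPM and Elane 0.585 CPM in the 9 hepatectomy libraries of POD2 to POD4. Mki67 had a mean of 34.8 CPM there and Top2a of 26.7 CPM, although Prtn3, another gene of primary granules, had a mean of 3.67 and reached 9.06 CPM. At POD1 too Mki67 stood above sham, at 20.1 to 28.3 against 5.16 to 14.3 CPM of the unscaled total. Its level alone therefore does not set POD2 to POD4 apart. Per unit of the score within groups, S phase members changed by a median of 0.365 on the log2 scale (25 of 40 rose and 0 fell) while all 14 neutrophil markers fell, which goes against precursors that follow the neutrophil content as the main source of S phase transcripts. Of the G2 and M phase members 3 rose and 4 fell, in slopes pooled over both operations. After hepatectomy, the low-score replicate 1 had the lowest mean of this list, 2.48 against 3.70 and 2.62 at POD3. At POD4 it stood at 2.69 against 3.66 and 4.10. In sham POD4 the low-score replicates 2 and 3 stood higher, at 2.14 and 3.5 against 1.74. The operations thus went opposite ways, each on single libraries. For the difference between the operations, cycling cells of another type and neutrophil precursors therefore cannot be told apart, and a response of the sorted cells stays open.

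Few genes passed at POD2, POD3 and POD4. The spread of endothelial content within groups is a candidate explanation: with the score in the model 1149, 1255 and 26 genes passed, while the highest of 99 shuffles of the score within groups gave 318, 334 and 30. As many genes as with the real score came in 1, 1 and 2 of 100 draws, the real score included. The score followed the first principal component (Pearson's r = 0.987), so the shuffles cannot tell endothelial content from another trait along that component. At POD2 the scores of the operations also do not overlap. The tables argue against an exchange of replicate 1 between hepatectomy and sham POD4, since all 3 genes called at POD3 lay above every sham POD4 library in that hepatectomy library, Col1a1 at 70.6 against at most 20.8 CPM. A fit of POD2 by itself called 3816 genes, against 2046 in such a fit of POD1, so the low count at POD2 comes with the fit of all 24 libraries, while a weaker effect of hepatectomy stays open for POD3 and POD4.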

How the results depend on the processing

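Of the alternatives, the endothelial score as a covariate and the fit without low-endothelial libraries of POD3 and POD4 were chosen after seeing the data; the others were planned. The POD1 count stayed at 2046 genes or more under every setting, while the counts of POD2, POD3 and POD4 changed with the tool, and the cause was not tested unless stated. Depth limits genes near the floor of 3 counts, and in the simulated counts of the self-test edgeR with 8 groups missed most 2-fold changes on a day.

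Main counts were 5866 genes at POD1, 14 at POD2, 3 at POD3, 0 at POD4 (689 at an unadjusted p under 0.05), 2009 in the mean, 1244 in the interaction, 4078 for POD4 minus POD1, 0 between sham days (2810 at an unadjusted p under 0.05) and 6422 between hepatectomy days. DESeq2 gave 195 at POD2, 277 at POD3, 31 at POD4, 3253 in the mean, 3320 in the interaction and 1513 between sham days. Limma voom with quality weights gave 4686 at POD2, 3776 at POD3, 7250 at POD4, 5207 in the mean, 10368 in the interaction, 8711 for POD4 minus POD1, 10039 between sham days and 11980 between hepatectomy days. DESeq2 size factors in edgeR gave 30 at POD2 and 1 between sham days. Library size alone gave 4 at POD2, 5 at POD3, 3050 in the mean, 2533 in the interaction and 6784 for POD4 minus POD1. No low-count filter gave 7 at POD2, 673 in the interaction and 1 between sham days, and at least 5 CPM in at least 3 libraries gave 23 at POD2, 2 at POD4 and 1 between sham days. A fit of each day by itself gave 2046 at POD1, 3816 at POD2 and 0 at POD3. The replicate block gave 2526 at POD1, 0 at POD2, 0 at POD3, 503 in the mean, 56 in the interaction and 613 for POD4 minus POD1. Equal replicate numbers share no source in the labels, and their residual correlation within a day ran from -0.85 to 0.171, with 3 of 12 best with their own number. Between days it exceeded 0.1 in 15 of 36 pairs, with 0.833, 0.767 and 0.567 for hepatectomy POD3 with POD4. The endothelial score as a covariate gave 1149 at POD2, 1255 at POD3, 26 at POD4, 4860 in the mean, 4898 in the interaction and 89 between sham days. Leaving out the low-endothelial libraries gave 166 at POD3, 4908 in the mean, 3828 in the interaction, 2650 for POD4 minus POD1 and 1665 between sham days, with a lone sham library at POD4 assumed to vary like the other groups.

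Of 136 list tests by day 83 were called. With an estimated correlation 0 were called, with fry 21, and with the endothelial score 54. The rule named 39 gene calls, of which between 27 and 39 kept call and direction under the alternatives fitted to all comparisons.

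Leaving out 1 library gave 3324 (without sham replicate 3) to 6760 (without sham replicate 1) genes at POD1, 0 (without sham replicate 2) to 15 at POD2, 0 (without hepatectomy replicate 3 or any sham library) to 18 (without hepatectomy replicate 1) at POD3, and 0 to 2 (without sham replicate 3) at POD4. The mean held 1488 (without sham POD2 replicate 3) to 3073 (without sham POD4 replicate 3) genes, the interaction 453 (without hepatectomy POD1 replicate 1) to 4744 (without sham POD4 replicate 1), and POD4 minus POD1 1836 (without sham POD1 replicate 3) to 7100 (without sham POD4 replicate 1). Between sham days 0 to 3449 (without sham POD4 replicate 1) genes passed, and between hepatectomy days 3053 (without hepatectomy POD1 replicate 1) to 7526 (without hepatectomy POD3 replicate 1). List calls ran from 77 to 86 and kept gene calls from 34 to 39.

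With the endothelial score the medians of 9, 5, 8 and 15 of 34 lists changed sign on POD1 to POD4, of which 8, 1, 3 and 6 had been called without it. At POD1 these included, before subtraction, neutrophil markers (-0.65), neutrophil receptors (-0.51), suppressive effectors (-0.32) and immediate-early genes (-0.39). Lipid genes (-0.20), interferon-stimulated genes (-0.05) and angiogenic factors (-0.03) were among them too, and none was called with the score. Neutrophil markers were at -0.35 at POD3, and granule genes at 0.08 and suppressive effectors at 0.43 at POD4. Among lists called in both fits the neutrophil receptors turned to -0.45 at POD3 and 0.50 at POD4, and the neutrophil markers to 0.51 at POD4. Vegfa at POD1 was at -1.21 with the score. With voom Il1b at POD3 was at -1.10.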

Other observations

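The endothelial score in the model and the counts over other splits were chosen after seeing the results, while the marker lists were planned. At POD2 the scores of the operations do not overlap. There, with that score, 26 of 40 S phase genes, 21 of 44 inflammatory genes, 18 of 28 neutrophil receptors, and 18 of 40 glycolysis genes (with 1 lower) passed as higher after hepatectomy. So did 14 of 32 suppressive effectors and 9 of 14 neutrophil markers. Vegfa, the main angiogenic growth factor, was at 1.71 ± 0.31 (adjusted p = 0.00345), Cxcl2 at 2.66 ± 0.53 (adjusted p = 0.007), and Itgam at 1.75 ± 0.44 (adjusted p = 0.0208). Tnf was at 2.36 ± 0.60 (adjusted p = 0.0222), Mmp9, a matrix protease of neutrophil granules, at 1.98 ± 0.49 (adjusted p = 0.0197), and S100a9 at 1.73 ± 0.47 (adjusted p = 0.0298). At POD1, where the score extrapolates and the operations do not overlap either, 42 of 73 oxidative phosphorylation genes were higher and 3 lower. Of 29 hepatocyte markers 20 were lower and 0 higher there. None of these list calls held with an estimated correlation.

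Erythroid markers were lower at POD2 (median -0.73, camera adjusted p = 0.00426, adjusted p = 0.37 with an estimated correlation) and at POD3 (median -0.59, camera adjusted p = 0.00234, adjusted p = 0.361 with an estimated correlation), a call that ended without replicate 1 of hepatectomy. The POD3 median was -1.01 without replicate 2 of hepatectomy. Cholangiocyte markers, a list that includes Spp1, had medians of 1.33 at POD2 and 1.75 at POD3 (camera adjusted p = 0.00151 and 0.00029, adjusted p = 0.361 and 0.334 with an estimated correlation). At POD3 this rested on replicate 1 of hepatectomy, the library with hepatocyte transcripts, without which the median was 0.63 and not called, and with the endothelial score it was 0.95 and not called (camera adjusted p = 0.422). Spp1 stood at 227 ± 80.0 CPM after hepatectomy and 13.3 ± 5.43 CPM in sham at POD2.

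Other splits of the same libraries were counted with edgeR. At POD1, POD2 and POD3 the real split gave 5866, 14 and 3 genes and the highest of the other 9 gave 0, so in each case 1 of 10 splits gave as many, but 10 splits are too few for a share under 0.05. At POD4 the real split gave 0 genes, so 10 of 10 splits gave as many by construction, which tests nothing, while the split of hepatectomy replicates 2 and 3 with sham replicate 1 against the rest gave 8220, which points to a structure of the samples that follows the endothelial score. For the mean over days 1 of 100 relabellings gave as many as the real 2009, with 315 as the highest other, so chance is excluded at that level. Between hepatectomy days 3 of 100 gave as many as 6422, with 8650 as the highest other, and between sham days the real count of 0 means that 100 of 100 gave as many by construction, with 7857 as the highest other.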
